A study of Mus musculus with 14 samples.

How the data were processed

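Total RNA from tumours of 14 mice was measured on Affymetrix mouse expression arrays, which carry short probes grouped into probesets near the 3' end of each transcript. The labels put 7 arrays in a control group and 7 in a group lacking HIF-2α, the oxygen-regulated transcription factor encoded by Epas1. The mice had a mixed background of different inbred strains. RNA was extracted with Trizol and biotin-labelled cRNA was hybridised, per the labels' protocols. Neither the organ of the tumours, the age of the mice nor the part of Epas1 that was lost is given in the sources used here.

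The deposited values are log2 probeset levels made by the authors with GCRMA, per the submitters' processing notes. GCRMA subtracts a background predicted from probe sequence, normalises between arrays and summarises the probes of each probeset. Its software version is not given in the sources used here. The log2 values ran from 2.12 to 15.4, and 43.9% of them lay under 4, where values pile up at the background that GCRMA sets. A level near that floor is a bound and a log2 difference against it depends on the floor. Array medians lay between 5.19 and 5.29 in controls and between 5.13 and 5.20 in deficient arrays. The share of probesets above 4 was 56.1% to 56.8% in controls and 55.7% to 56.1% in deficient arrays. Both measures thus tended slightly lower in the deficient group, and the cause was not tested. For arrays the number of arrays limits the precision. The median standard error of a log2 difference between groups was 0.18, and 4.83% of the tested probesets had a standard error above 0.5.

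The table held 22690 probesets, of which 64 were Affymetrix controls. The platform annotation, which can be old, gave 1 gene for 20380 probesets, several genes for 691 and none for 1555. Of the probesets with 1 gene, 20351 had a gene ID in the RefSeq gene table of assembly GRCm38.p6. Symbols were updated for 0 of them, and 29 probesets kept the platform's symbol. A gene with several probesets was represented by the one with the highest mean over all 14 arrays, and probesets naming several genes or none were counted but not named by gene. That gene table was used only for names and for which genes neighbour each other, since the labels name no genome build.

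Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with 1 group term was fitted to the deposited values (lmFit), the variances were moderated (eBayes), tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the probesets tested. The threshold was an adjusted p under 0.05. Probesets were tested if they were not controls and had a value above 4 in at least 7 of the 14 arrays, which kept 12701 probesets and left out 9925. Differences are deficient minus control on the log2 scale, with the standard error (SE) of the fit, and group values are means ± SD over 7 arrays.

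For gene lists, 39 lists of cell type markers, pathways and complexes were fixed, with 930 symbols, of which 20 were matched through a synonym and 3 were not matched. The 30 lists with at least 5 tested members were tested. The score of an array was the mean over members of the value minus the member's mean over arrays. Group means of the score were compared by a two-sided exact permutation test over the 3432 splits of the 14 arrays into 7 and 7, adjusted over the 30 lists. The smallest p this test can give is 0.000583. Single members were also adjusted over the list alone. Camera, with a preset correlation of 0.01 and with an estimated correlation, and fry were run as alternatives. RNA quality was read as the mean log2 difference between the 3' and 5' control probesets of 4 genes (Gapdh, beta-actin, pyruvate carboxylase and transferrin receptor), compared by an exact permutation test. Called genes within 20 Mb of Epas1 were compared with other genes by Fisher's exact test. After the data were seen, the mean of the genes in that window less the mean of all other tested genes was also compared between groups by the exact permutation test. The same difference was taken for windows around each tested gene on other chromosomes that held at least 28 genes.

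The genes named follow a rule. It takes 9 genes of oxygen sensing or reported by the study (Epas1, Hif1a, Hif3a, Arnt, Vhl, Egln1, Egln3, Vegfa and Scgb3a1). It then takes up to 12 called genes with the largest difference in each direction, filled up to 6 by the smallest p where fewer pass. For each list described it takes the 3 members with the smallest p and the 1 with the highest mean level. Groups, lists, tests, this rule and most alternatives were fixed before the data were examined. Alternatives covered the filter, the normalisation between arrays, the variance model, array weights, array numbers, sex-linked signal, RNA quality, the threshold and each array left out in turn.

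The description of each array in the labels holds a number whose leading digits are shared by several arrays, and no source used here says what they mean. Arrays sharing these digits lie within 1 group, so they were treated as a possible batch, once as a random block (duplicateCorrelation) and once by averaging. All controls and deficient 4 and 7 are numbered in 1 style, and deficient 1, 2, 3, 5 and 6 in another that no control has. An origin that followed this style would be partly confounded with the group. The alternative without the 2 deficient arrays numbered in the controls' style keeps only deficient arrays of the other style, so it cannot separate the 2. A further number runs in 1 block through the deficient arrays and then through the controls, so an order of handling that followed it cannot be told apart from the group. The replicate numbers of the titles only name arrays. No array was a copy of another's values: at most 0.693% of the values of any pair were identical. This check cannot show whether arrays share a tumour or an RNA sample. Controls 2, 5 and 7, which share a leading number, correlated with each other at r = 0.987 to 0.991.

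The fit was tested on simulated data for the deficient against control comparison with 12701 probesets. It recovered 56% of probesets changed 2-fold and 95% of those changed 4-fold, with 8 false calls, and made 0 calls where nothing was changed. The list test recovered 10 of 10 lists shifted by 1 log2 unit and called 1 of 20 others. Most real lists shifted by less, and recovery of smaller shifts was not simulated. The simulated noise was independent between probesets and arrays, and every member of a shifted list moved by the same amount. In the real data the estimated correlation within the endothelial list was 0.762, and that of arrays sharing a leading number was 0.349. These simulated rates therefore need not hold for the real arrays.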

Results

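Tumours from 7 control mice and 7 mice deficient in HIF-2α were profiled on arrays, to ask which transcripts in the tumours depend on this transcription factor. HIF-2α pairs with ARNT and activates genes when oxygen is low. The labels call the second group both deficient and a knockdown, and "deficient" is used here. The study is known for its work on lung tumours, but the labels do not name the organ. Probesets with high values in both groups included those of surfactant protein A1 (Sftpa1, 13.98 ± 0.11 in controls and 13.94 ± 0.19 in deficient tumours, SD, n = 7 each) and the club cell secretoglobin Scgb1a1 (13.78 ± 0.05 and 13.84 ± 0.26). Arrays of the control group correlated with each other at r = 0.923 to 0.991 across probesets, and those of the deficient group at 0.839 to 0.971. These correlations are across probesets, which are not independent replicates.

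The 14 arrays carry 6 leading numbers in their descriptions, 2 among controls and 4 among deficient arrays. Within groups, arrays with a shared number deviated from their group mean together more than other pairs did (mean r 0.112 against -0.283, one-sided exact permutation p = 0.000454). The series design speaks of 7 mice per group, but if a shared number marks a shared origin, the arrays are fewer independent samples than 14. The p-values below measure the spread between these arrays. Eif2s3y, a gene on the Y chromosome, was above background in 4 arrays, 2 of each group.

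The target gene was examined first. The single Epas1 probeset read 5.84 ± 0.69 in controls and 5.65 ± 0.51 in deficient tumours, a difference of -0.19 (SE 0.30) that was smaller than the spread between arrays (limma adjusted p = 0.807). Its 95% interval was -0.84 to 0.46. Values ran from 4.65 to 6.50 in controls and from 4.88 to 6.38 in deficient arrays, so the ranges of the groups overlapped. A probeset that lies outside the deleted part of a gene checks nothing, and the sources used here do not give that part, so this value neither bears out nor contradicts the labels.

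Between deficient and control tumours 5 probesets passed the threshold, 2 higher and 3 lower in deficient. Mocs1, which encodes an enzyme of molybdenum cofactor synthesis, rose from 5.41 ± 0.30 to 7.00 ± 0.58, a difference of 1.59 (SE 0.23, 3.02-fold, limma adjusted p = 0.0325). Ctnnal1, which encodes alpha-catulin, rose from 7.29 ± 0.23 to 8.19 ± 0.28, a difference of 0.90 (SE 0.14, 1.87-fold, adjusted p = 0.0359). Aoc1, which encodes the diamine oxidase that degrades histamine and putrescine, fell from 8.36 ± 0.93 to 4.61 ± 1.32, a difference of -3.75 (SE 0.56, adjusted p = 0.0325), with 3 of the 7 deficient arrays under 4. Fbxo36, an F-box protein gene, fell by 2.00 (SE 0.30, adjusted p = 0.0325) in 1 probeset. Its brighter probeset, which represents the gene, differed by -1.53 (SE 0.26) and did not pass (adjusted p = 0.0601). The remaining call, lower in deficient, was a probeset that matches several genes and so has no single name. This probeset and the second Fbxo36 probeset fall outside the naming rule and were chosen after their values were seen. Each of Mocs1, Ctnnal1 and Aoc1 moved in its direction in 7 of 7 deficient arrays against the control mean. Genes picked for a small p in the same arrays tend to do so, and this count adds no support.

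These calls were few and changed with the arrays used. With 1 array left out at a time, Mocs1 and Aoc1 passed in 8 of 14 fits, not without control 2, 5, 6 or 7 or deficient 2 or 4. Ctnnal1 passed in 6 of 14, not without those or without control 1 or deficient 5. With the leading number as a random block 0 probesets passed, and the adjusted p was 0.613 for Mocs1, 0.613 for Ctnnal1 and 0.543 for Aoc1, while their differences were 1.62, 0.93 and -3.61. Leaving out 1 array gave 1 probeset without control 2, 5, 6 or 7 in turn and 0 without deficient 2 or 4. It gave 85 without control 4, 30 without deficient 6, 13 without deficient 7 and 11 without deficient 1. At an unadjusted p under 0.05 there were 1863 probesets, 1028 higher and 835 lower, where chance alone gives 635. The median log2 difference over all tested probesets was 0.02.

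**Figure D1:**
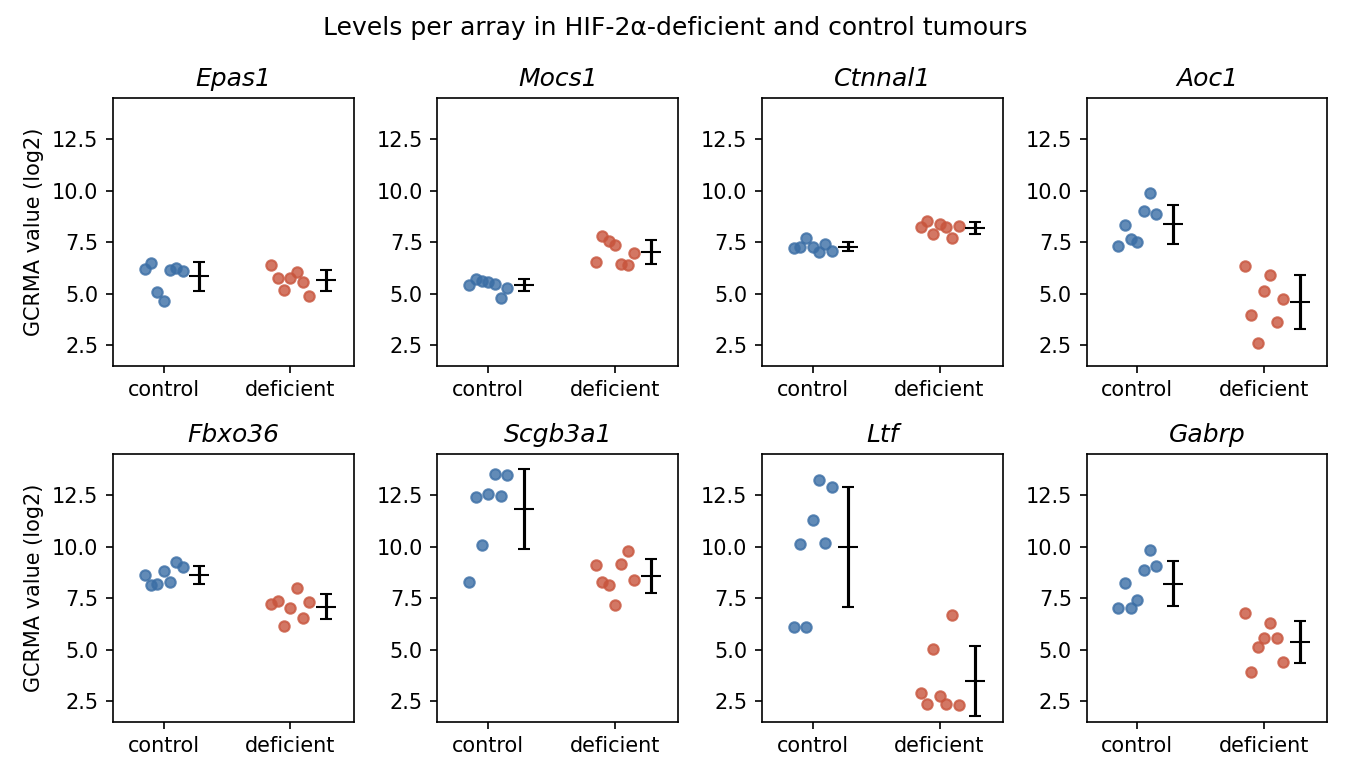
GCRMA level (log2) of 8 genes in each of the 7 control and 7 deficient arrays, with the mean and SD of each group as a bar beside the points. The groups do not overlap for Mocs1, Aoc1, Fbxo36 or Gabrp, while Epas1 lies between 4.65 and 6.50 in all arrays.

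The genes next in order did not pass the threshold. On the higher side they were Mphosph6 (0.74, SE 0.13, limma adjusted p = 0.0601), Prune1 (0.54, SE 0.11), Ypel5 (0.47, SE 0.09) and Haus6 (0.77, SE 0.16), the last 3 with an adjusted p of 0.111. On the lower side stood the lipid-binding protein gene Sec14l2 (-1.74, SE 0.30, adjusted p = 0.0601) and Camsap1, which encodes a binder of microtubule ends (-0.70, SE 0.13, adjusted p = 0.111). The widest gap was that of lactotransferrin (Ltf), an iron-binding protein of secretions and neutrophil granules, at 10.01 ± 2.92 in controls and 3.49 ± 1.70 in deficient tumours (-6.51, SE 1.16, adjusted p = 0.0787). It lay under 4 in 5 of 7 deficient arrays. Gabrp, which encodes the pi subunit of the GABA-A receptor, read 8.22 ± 1.10 and 5.39 ± 1.00 (-2.83, SE 0.51, adjusted p = 0.0798), and both of its probesets differed in the same direction.

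Genes of the secretory cells of the airway lay lower in deficient tumours. Of the 16 tested markers of club and secretory epithelium 15 were lower, 11 at an unadjusted p under 0.05. Adjusted over the list alone 10 fell, and over all probesets tested 0 did. The list's mean shift was -1.74, with scores below the control mean in 7 of 7 deficient arrays (exact permutation p = 0.00175, adjusted p = 0.0524), so it missed the threshold. Scgb3a1, a secretoglobin that the study's own report names as lowered, read 11.84 ± 1.93 in controls and 8.59 ± 0.85 in deficient tumours (-3.25, SE 0.73, limma adjusted p = 0.116, exact permutation p = 0.00408). It was below the control mean in 7 of 7 deficient arrays. Because the study found Scgb3a1 in these samples, its value is not independent evidence. Control 1, at 8.32, lay within the deficient range, and without it the difference was -3.84 with an adjusted p of 0.0346. That was the 1 of 14 fits with an array left out in which Scgb3a1 passed, in a range of 0.0346 to 0.280. Haptoglobin (Hp) read 13.11 ± 0.22 and 12.46 ± 0.27 (-0.66, SE 0.14), while Scgb1a1, the brightest member, differed by 0.06 (SE 0.11).

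Markers of ciliated airway cells lay lower in the same arrays. All 6 tested members were lower, and 6 fell adjusted over the list alone against 0 over all probesets tested. The mean shift was -2.18 (exact permutation p = 0.00699, adjusted p = 0.105), below the control mean in 7 of 7 deficient arrays. Tppp3, a tubulin-binding protein gene, read 10.27 ± 0.95 and 7.95 ± 1.37 (-2.32, SE 0.57), Lrrc23 differed by -3.49 (SE 0.99) and Rsph1, a component of the ciliary radial spoke, by -2.70 (SE 0.80). The abundant tubulin gene Tubb4b differed by -0.35 (SE 0.16). With the ciliated score as a covariate, a test chosen after the results were seen, the difference was -1.91 for Aoc1 (95% interval -2.76 to -1.05), -1.29 for Gabrp (-2.32 to -0.25), -0.90 for Fbxo36 (-1.57 to -0.24), 1.13 for Mocs1 (0.47 to 1.79) and 0.92 for Ctnnal1 (0.48 to 1.36). It was -5.79 for Ltf (-9.8 to -1.8), -1.70 for Sec14l2 (-2.73 to -0.67) and -1.98 for Scgb3a1 (-4.23 to 0.26), whose interval includes 0. Except for Scgb3a1, these genes were picked for a small p in the same arrays. The intervals also take the 14 arrays as independent. They therefore do not settle whether these genes differ beyond the amount of airway tissue. Camera with an estimated correlation gave an adjusted p = 0.321 for the club list and an adjusted p = 0.387 for the ciliated list. With arrays averaged over the leading number the shifts were -1.60 and -1.97, with exact permutation p-values of 0.0667, the smallest that 6 numbers allow, and 0.267. Without control 1 the club list passed with an adjusted p of 0.0175, in a range of 0.0175 to 0.0874 over the single arrays left out.

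**Figure D2:**
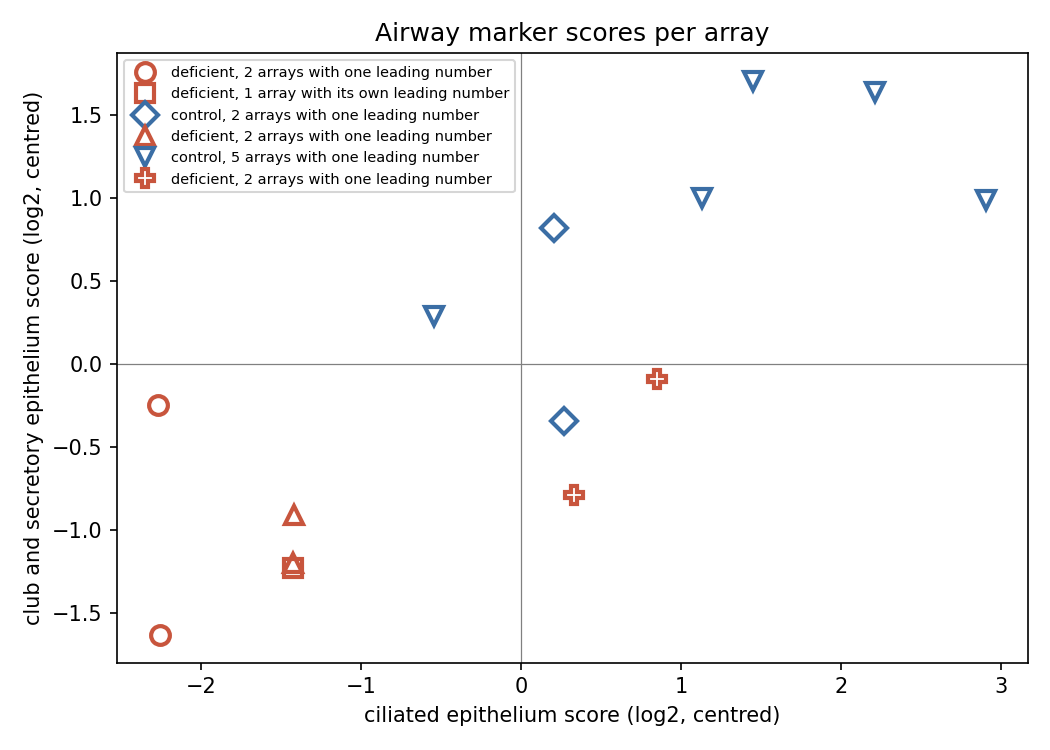
Score of the club and secretory epithelium list against that of the ciliated epithelium list for each array (log2, centred over arrays), with blue for control and red for deficient and 1 marker shape per leading number. The 7 deficient arrays all lie below 0 on the club axis, and so does control 1, at -0.34.

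Alveolar markers gave no shift past the threshold. The alveolar type II list, 20 genes of the surfactant-making cells, had a mean shift of -0.003 (exact permutation p = 0.977), a value whose sign changed with the processing, and its median member differed by 0.03. Its members Egfl6 (0.45, SE 0.21), Cxcl15 (0.21, SE 0.10) and complement component Hc (-0.61, SE 0.29) had an adjusted p of 0.335, 0.339 and 0.347. The 12 alveolar type I markers had a mean shift of -0.43 (exact permutation p = 0.114, adjusted p = 0.264), with Igfbp2 at -2.76 (SE 0.81), Rtkn2 at -1.50 (SE 0.64), Hopx at -0.70 (SE 0.35) and Cldn18 at 0.07 (SE 0.12, with -0.33 in its other probeset). That shift was -0.28 without deficient 6 and -0.07 without deficient 3 and 6, an alternative chosen after seeing the data here and below.

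Lists of vessel and connective tissue genes lay lower without passing. Of 25 endothelial markers 24 were lower, with a mean shift of -0.61 that was small beside the spread of deficient scores (SD 1.25, exact permutation p = 0.259). That shift was -0.33 without deficient 3 and 0.02 without deficient 3 and 6. Among them Sox18, a transcription factor gene of vessel development, differed by -1.05 (SE 0.33), Edn1, which encodes endothelin-1, by -1.13 (SE 0.45), the VEGF receptor gene Flt1 by 0.41 (SE 0.20, with -0.36 in its other probeset) and Cd93, the brightest, by -0.07 (SE 0.32). Of 25 fibroblast and matrix genes 21 were lower (mean shift -0.52, exact permutation p = 0.0507, adjusted p = 0.242), with a shift of -0.34 without deficient 3 and -0.24 without deficient 3 and 6. The collagen VI genes Col6a1 and Col6a2 differed by -1.07 (SE 0.36) and -1.17 (SE 0.44), Loxl1 by -0.72 (SE 0.25) and Sparc by -0.03 (SE 0.10). The 6 mesothelial genes had a mean shift of -0.41 (exact permutation p = 0.0967), or -0.26 without deficient 2, with Igfbp6 at -0.93 (SE 0.50), Gpm6a at -0.82 (SE 0.59), Igfbp5 at -0.80 (SE 0.59) and Krt18 at 0.14 (SE 0.21).

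Among leukocyte lists, 17 of 20 macrophage genes were lower (mean shift -0.34, exact permutation p = 0.0659, adjusted p = 0.247). Adgre1, which encodes the macrophage antigen F4/80, differed by -0.78 (SE 0.28), the alveolar macrophage lectin Siglecf by -1.27 (SE 0.48), Fabp5 by 0.35 (SE 0.15) and the bright Chil3 by -0.26 (SE 0.25). The 7 neutrophil genes had a mean shift of -0.90 (exact permutation p = 0.0216, adjusted p = 0.197) but a median member difference of 0.24. The mean followed Ltf, the 1 member that fell adjusted over the list alone, and Ltf is also made by secretory epithelium. Fpr2 differed by -1.32 (SE 0.80), Il1b by 0.56 (SE 0.42) and the granule protein gene S100a9 by 0.24 (SE 0.46).

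Genes of oxygen sensing and of the response to low oxygen gave no call. The 6 HIF core genes had a mean shift of -0.21 (exact permutation p = 0.0262, adjusted p = 0.197) but a median member difference of -0.04, with 3 members higher and 3 lower. The mean followed Per1, the member with the widest difference, so it does not show a fall of the oxygen-sensing genes as a set. Adjusted over the list alone, Per1, a circadian clock gene kept there for its PAS domain, fell by 1.37 (SE 0.34), and Hif1a, which encodes HIF-1α, rose by 0.32 (SE 0.11). Over all probesets the adjusted p was 0.132 for Per1 and 0.219 for Hif1a, and the other tested probesets of Hif1a differed by -0.01 and -0.70. The prolyl hydroxylase genes Egln1 and Egln2 differed by 0.11 (SE 0.16) and -0.30 (SE 0.13), Cited2 by 0.15 (SE 0.16, with -0.12 in its other probeset) and Vegfa by 0.17 (SE 0.12, with -0.58 in its other probeset). Probesets of Hif3a, Arnt and Vhl lay near the background floor, with group means of 2.14 to 2.47. Egln3 was also left out by the filter, at 2.72 ± 0.32 in controls and 3.50 ± 1.64 in deficient tumours. Hif3a, Arnt, Vhl and Egln3 were therefore not tested.

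The 15 tested genes listed as HIF-2 targets had a mean shift of 0.07 (exact permutation p = 0.605, adjusted p = 0.790), with 9 higher and 6 lower. The shift was 0.01 without control 5, 0.12 without deficient 3 and 0.19 without deficient 3 and 6. Edn1 at -1.13 was also in this list, beside Lox, which encodes a collagen cross-linking oxidase (0.44, SE 0.18), and the cyclin D1 gene Ccnd1 (0.24, SE 0.10). The less bright probesets differed by 0.07 for Lox and by 0.79 and 0.65 for Ccnd1 (limma adjusted p = 0.116 and 0.111). Of 24 genes of hypoxia and glycolysis 19 were higher (mean shift 0.26, exact permutation p = 0.111, adjusted p = 0.264). Ero1a, an oxidase gene of the endoplasmic reticulum, differed by 0.61 (SE 0.17), Pdk1 by 0.73 (SE 0.27), the glucose transporter gene Slc2a1 by 0.58 (SE 0.23) and Aldoa by 0.11 (SE 0.11). Deficient 3, at 0.91, held the highest score of this list, and the shift was 0.13 without it and 0.06 without deficient 3 and 6.

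Growth-related lists were likewise under the threshold. Of 17 genes of Ras and MAPK output 14 were higher, 8 of them at an unadjusted p under 0.05 (mean shift 0.30, exact permutation p = 0.0565, adjusted p = 0.242). Adjusted over the list alone, the feedback inhibitor gene Spry2 rose by 0.56 (SE 0.13) and the growth factor gene Ereg by 1.33 (SE 0.38). Over all probesets tested 0 members passed, and Egr1 differed by 0.55 (SE 0.20). Of 23 cell cycle genes 18 were higher (mean shift 0.25, exact permutation p = 0.301), with Mcm2 at 0.59 (SE 0.24), Mcm4 at 0.54 (SE 0.23), Tk1 at 0.58 (SE 0.26) and Pcna at -0.06 (SE 0.18). Its shift was 0.09 without deficient 4, 0.38 without deficient 6 and 0.39 without deficient 3 and 6. The 22 genes of AKT, mTOR and FOXO signalling had a mean shift of 0.05 (exact permutation p = 0.477), and 0.01 without control 6 or 0.08 without deficient 3, with Cdkn1b at 0.44 (SE 0.15, with -0.30 in its other probeset), Pik3ca at 0.35 (SE 0.12), Sesn3 at 0.42 (SE 0.16) and Foxo3 at -0.32 (SE 0.14). The 11 Wnt, Notch and Hedgehog genes had a mean shift of -0.38 (exact permutation p = 0.0513, adjusted p = 0.242). Notch1 fell by 0.55 (SE 0.16) adjusted over the list alone but did not pass over all probesets (adjusted p = 0.153), beside Hey1 at -1.23 (SE 0.52), Nkd1 at -0.57 (SE 0.28) and Notch2 at 0.07 (SE 0.11). The 12 genes of EMT and invasion had a mean shift of -0.32 (exact permutation p = 0.0962), or -0.18 without deficient 3 and 6, with the gelatinase gene Mmp2 at -1.45 (SE 0.46), Tgfb1 at -0.37 (SE 0.31), Tgfbi at -0.47 (SE 0.40) and Vim at -0.17 (SE 0.18).

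Across the 30 lists 0 passed the threshold and 4 had an exact permutation p under 0.05, where chance gives 1.5. Camera with the preset correlation called 8 lists, with an estimated correlation 0, and fry, which asks whether a list's genes move one way on balance, called 2, the club and ciliated lists. For the 8 lists camera called, the adjusted p with an estimated correlation was 0.321 to 0.771. With no filter on low probesets, the shift was -0.04 for the HIF core, -0.46 for the neutrophil, -0.19 for the mesothelial, -0.09 for the EMT and -0.17 for the Wnt, Notch and Hedgehog list, and 0.12 for HIF-2 targets. The other 13 lists shifted by -0.46 to 0.09, with a smallest exact permutation p of 0.109. Another 9 lists had under 5 tested members, among them those of skeletal muscle, liver, kidney and squamous epithelium. The neuroendocrine list, with 1 tested member, passed with no filter (13 members, 11 lower, shift -0.38, exact permutation p = 0.000583, adjusted p = 0.0221), below the control mean in 7 of 7 deficient arrays, though 12 of these members lay above 4 in under 7 arrays. Chga, Chgb, Syp, Insm1, Scg2, Scg3, Pcsk1 and Neurod1 lay above 4 in 0 arrays, so their differences, such as -0.003 for Scg3, are differences at the floor. Resp18 read 4.04 ± 1.97 and 2.41 ± 0.41, and Uchl1 3.15 ± 1.09 and 2.40 ± 0.15, above 4 in only 2 arrays and 1 array. The shift of this list therefore does not show a fall of its genes as a set.

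**Figure D3:**
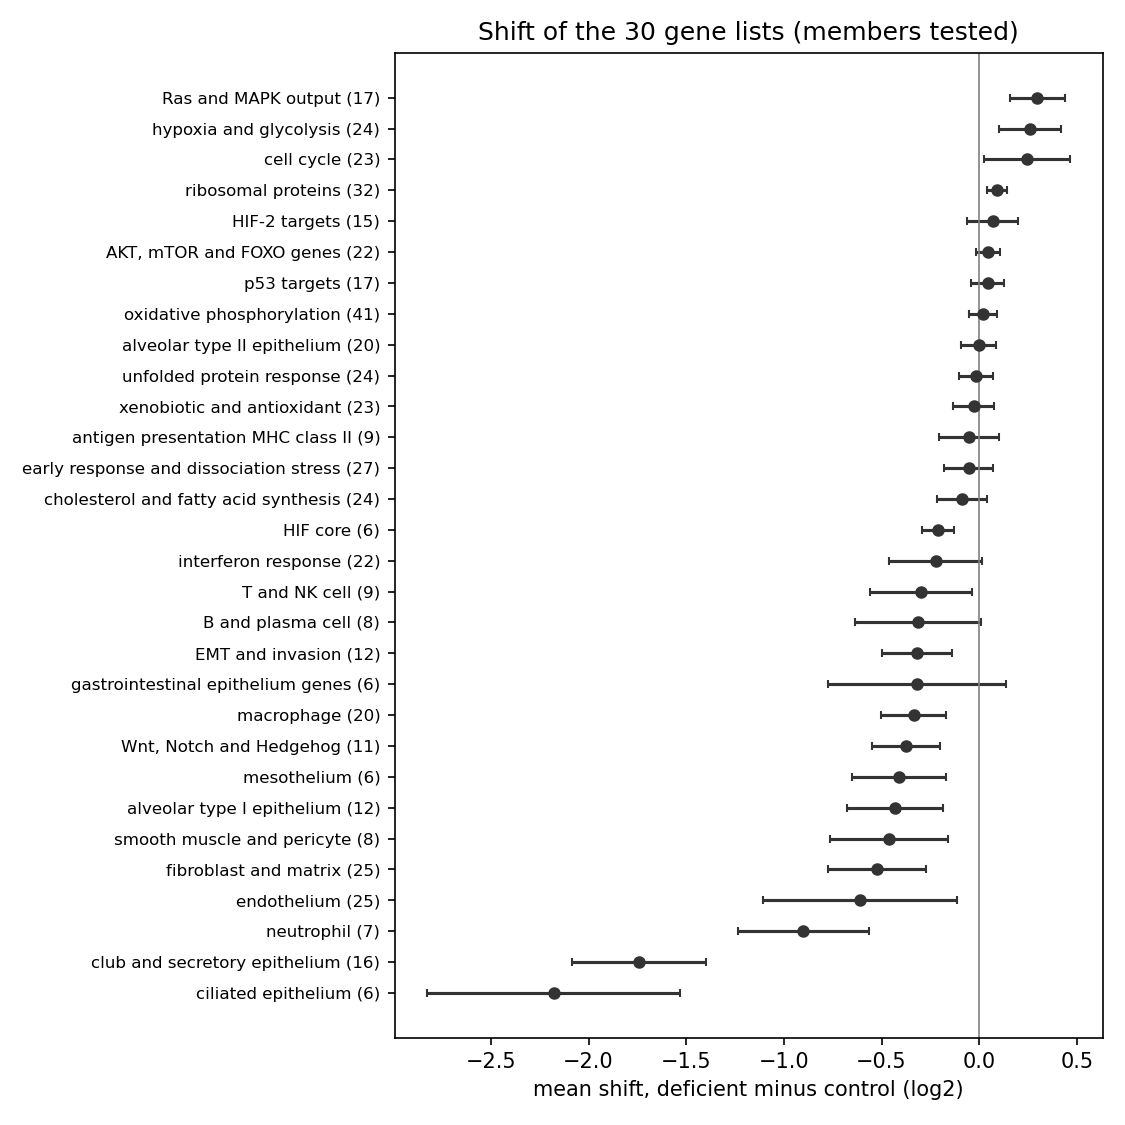
Mean shift of each of the 30 gene lists, deficient minus control (log2), with the standard error between arrays as a bar and the number of tested members in brackets. The ciliated and the club and secretory lists lie farthest from 0, at -2.18 and -1.74.

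RNA quality did not separate the groups. The mean 3' minus 5' difference was 2.87 ± 0.34 in controls and 2.80 ± 0.23 in deficient arrays (-0.07, exact permutation p = 0.692), and without control 1 the difference was 0.04. The 4 genes behind this mean went both ways, at -0.12 for Gapdh, -0.10 for beta-actin, -0.42 for pyruvate carboxylase and 0.36 for transferrin receptor (exact permutation p = 0.213 to 0.612). Because a targeted gene can keep flanking sequence of the donor strain, genes near Epas1 were compared with the rest. Only 3 genes were called in all, so their counts, 0 of 56 genes within 20 Mb and 1 of 113 within 40 Mb (Mocs1), decide little. At an unadjusted p under 0.05, 13 of 56 genes (23.2%) stood against 15.1% of the others (Fisher's exact p = 0.0941). For the count within 40 Mb, which rests on Mocs1 alone, Fisher's exact p was 0.0431. Within 20 Mb the median log2 difference was 0.18, against 0.001 for the other genes. In a test chosen after this was seen, the mean of the near genes less that of the others differed by 0.23 between groups (exact permutation p = 0.00641), above the control mean in 7 of 7 deficient arrays. Of 7341 overlapping windows of this width on other chromosomes, 0.109% differed by as much in either direction. Within 40 Mb, which holds Mocs1, the difference was 0.20 (exact permutation p = 0.000583, the smallest this test can give), above the control mean in 7 of 7 deficient arrays, and 0% of 7330 other windows differed by as much. In a comparison that was not planned, the 391 genes of chromosome 17, where Epas1 lies, shifted by 0.12 (exact permutation p = 0.0863, adjusted p = 0.288), the widest shift of any chromosome. Chromosomes 13 (0.10), 12 (-0.10) and 15 (-0.09) shifted nearly as far, with exact permutation p-values of 0.0239, 0.0583 and 0.0583, so chromosome 17 did not stand out. A shift along the whole of chromosome 17 was not told apart from one near Epas1. Averaged over the leading number, where no p under 0.0667 is possible, the difference within 20 Mb was 0.26 (exact permutation p = 0.267), and without deficient 2, the highest array, it was 0.16 (exact permutation p = 0.0134).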

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

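The covariate tests of the airway genes, the test of Y-linked signal within leading numbers and the test for a mixed-in Y-bearing sample were chosen after the results were seen. Of 82 groups of 7 arrays examined, 4 held 1 array far from the other 6, where chance gives about 5%, which is 4.1 groups.

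Mphosph6 stood at 7.32 in deficient 3, against 6.49 to 6.78 in the other deficient arrays. Sec14l2 stood at 9.33 in control 1, against 7.39 to 8.22 in the other controls. The score of the Ras and MAPK list was 0.31 in control 3, against -0.34 to -0.11 in the other controls. The same score was -0.47 in deficient 1, against 0.08 to 0.47 in the other deficient arrays.

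The first pattern is the lower level of airway secretory genes, with a club list shift of -1.74. RNA degradation, as read by the 3' minus 5' difference, is argued against as the whole cause, since that difference did not separate the groups (-0.07, exact permutation p = 0.692). Given it, -1.74 remained (95% interval -2.53 to -0.94, or -3.02 to -0.04 averaged over the leading number). A covariate that differs so little between the groups could remove little, so this model adds little to that. A smaller share of normal lung was read only through the endothelial score, given which -1.63 remained (-2.44 to -0.82, or -2.75 to -0.24 averaged). That score separated the groups little (exact permutation p = 0.259), so a model with it could remove little. Airway cells are also part of normal lung, so this does not settle its share. Less airway tissue in the sampled tumours stays open: given the ciliated score -1.08 remained over 14 arrays (-1.97 to -0.18), but averaged over leading numbers -1.02 with an interval of -2.23 to 0.20. For Scgb3a1 alone -1.98 remained given the ciliated score (-4.23 to 0.26) and -3.23 given the endothelial score (-5.17 to -1.29, but -5.71 to 0.07 averaged), so for this gene neither can be told apart from a change within the cells, the first because its interval includes 0 over the 14 arrays already and the second because the leading numbers are too few. Loss of HIF-2α in secretory cells, and differences between the animals, may also account for the pattern and were not tested apart.

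The second pattern is that arrays with a shared leading number are alike, by a difference in mean correlation of 0.395 (one-sided exact permutation p = 0.000454), as a shared animal, litter or batch would give. The arrays of each of the 6 numbers, 1 of which holds a single array, lay on the same side of 4 in Y-linked signal, which a share of 0.00680 of the 13230 reassignments within groups gives, so several tumours of 1 animal per number is a candidate explanation, against the stated 7 mice per group. It stays unproven, since within 1 number Eif2s3y read 10.25 in control 1 and 7.84 in control 4, whose description has a suffix of unknown meaning. Of the 4 splits into 7 and 7 that keep the numbers whole, 2 called at least the real count of 5, the real one and another with 1318, which points to a structure of the samples that is not the group, and 0 probesets passed with the number as a random block. Among 100 splits drawn at random, the real one included, 3 called as many (highest other 53), but those break up the shared numbers, so chance is not excluded for this count, nor for the 1863 probesets at an unadjusted p under 0.05 (5 of 100, highest other 2764) or the 4 lists at an exact p under 0.05 (15 of 100, highest other 10).

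The third pattern is a low level of Xist, the RNA that coats the inactive X chromosome, at 7.94 in deficient 3 against 10.99 to 11.84 in the other arrays without Y-linked signal. RNA of a Y-bearing sample mixed in is argued against, since the difference of its Eif2s3y level from the highest of the other arrays at the floor was -0.008. Fewer copies of the X that bears Xist in these cells stays open: the mean of Kdm5c, Kdm6a and Eif2s3x, genes that escape X inactivation, was 7.92, against 8.10 to 8.42 in those other arrays, and 3 of the 4 arrays with Y-linked signal read 7.57, 7.73 and 7.81, but control 4, whose Y-linked signal was the lowest of these 4, read 8.14, so the measure did not keep the 4 arrays apart from those without. The low mean of deficient 3 rested on Kdm6a (6.43), which lay below all those other arrays without Y-linked signal, while Kdm5c (6.66) and Eif2s3x (10.69) lay within their range. No biological explanation from the design was tested. The array was also the farthest out on the first principal component, at 81.7, which held 39.2% of the variance.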

How the results depend on the processing

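The alternatives without deficient 3 and 6, with only the 10 arrays without Y-linked signal and for the mean difference of genes near Epas1 were chosen after seeing the data. Over the settings tried, with the single omissions that moved each result most, the genes named for oxygen sensing, by the study or by the group comparison kept direction and side of the threshold in 222 results, newly passed in 41, lost the call in 23 and reversed in 1, and the lists described did so in 316, 15, 0 and 20. The cause of a change was not tested, except that fewer arrays leave less power. Against 5 probesets (2 higher, 3 lower), 0 higher, 0 lower and 0 in all passed with no filter, with the leading number as a random block, with arrays averaged over it, without the 2 deficient arrays numbered in the controls' style and without the arrays with a suffix. Trend and robust eBayes gave 9 (6 lower), array weights 1900 (992 higher, 908 lower), Xist as a covariate 24 (6 higher, 18 lower), an adjusted p under 0.10 11 (8 lower), and the 3' minus 5' covariate 1 higher. Without deficient 3 and 6 there were 32 (12 higher, 20 lower) and with the 10 arrays without Y-linked signal 16 (4 higher, 12 lower), of which 0 were among the 5. Array weights were highest for control 2, 5 and 7 (3.71, 4.15 and 2.36). Over single arrays left out the count ran from 0 to 85 (higher 0 to 47, lower 0 to 38).

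The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.226 to 0.223, and 0 controls matched their own number best. With the replicate block 2 probesets passed (1 higher, 1 lower), 1 of them among the 5.

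Against 0 lists, 8 passed with camera's preset correlation, 2 with fry, 2 with members scaled to unit SD, 2 of the 38 then tested with no filter (club and neuroendocrine), 1 of 27 with values above 6, and 0 to 1 over single arrays left out. Near Epas1, 1 gene was called within 40 Mb. At an unadjusted p under 0.05 there were 13 of 56 genes within 20 Mb and 21 of 113 within 40 Mb. The mean difference of genes within 20 Mb, 0.23, ran from 0.165 to 0.267 over single arrays left out and from 0.162 to 0.286 over the other alternatives, and was 0.263 averaged over the leading number, where 6 numbers allow no p under 0.0667 and the threshold cannot be passed. The sign reversed for Egln1 (-0.0412) and the endothelial list (0.0237) without deficient 3 and 6, and for HIF-2 targets averaged over the leading number (-0.00840). The alveolar type II list, at -0.00277, was given a positive direction, under the threshold, by camera with both correlations and by fry, and read 0.22 with members scaled to unit SD, 0.0125 with the mean of each gene's probesets, 0.0109 with centred arrays, 0.0624 averaged over the leading number and 0.0669 without deficient 3 and 6, and -0.0391 to 0.0398 over single arrays left out. The unfolded protein response list, at -0.0159, was given a positive direction by camera with both correlations and by fry, and read 0.0485 with members scaled to unit SD, 0.0360 without the arrays with a suffix and -0.0634 to 0.0284 over single arrays left out. The p53 list read -0.0293 without the 2 deficient arrays numbered in the controls' style, -0.0323 with the 10 arrays without Y-linked signal and -0.0201 to 0.0915 over single arrays left out. Of the 30 lists, 14 moved by over 1.5 times and kept their sign with the 10 arrays without Y-linked signal, among them macrophage -0.51, EMT -0.51, T and NK cell -0.69 (exact permutation p = 0.0317), smooth muscle -0.10, Ras 0.20, HIF-2 0.16 and alveolar type II -0.0963. As many, 14, did so without deficient 3 and 6, 11 with no filter, 11 without the 2 deficient arrays numbered in the controls' style (Ras 0.19, cell cycle 0.09, B cell -0.16, interferon -0.34 among them), 7 without the arrays with a suffix (mesothelial -0.20, cell cycle 0.11, interferon -0.42 among them) and 5 of 27 with values above 6 (HIF-2 0.13, AKT 0.08, B cell -0.59 among them). The RNA quality difference ran from -0.125 to 0.0413 over single arrays left out, positive without control 1. Signal over background limits low genes: 9925 probesets were near the floor in most arrays and not tested.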

Other observations

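Lists not described above held a few members that fell adjusted over their list alone and not over all probesets tested, and the shifts of these lists did not pass. Ighm, the heavy chain of immunoglobulin M, read 12.33 ± 1.23 in controls and 10.47 ± 1.01 in deficient tumours (-1.85, SE 0.55, limma adjusted p = 0.162 over all probesets), and 8 of 8 of its tested probesets were lower. The other B and plasma cell genes went both ways, with Jchain at -0.75 (SE 0.33) and Cd79b at 0.32 (SE 0.15), and the list shifted by -0.31 (exact permutation p = 0.343; -0.16 without deficient 2 and -0.09 with no filter). Pigr, the receptor that carries polymeric immunoglobulin across epithelium, read 8.60 ± 1.15 and 5.70 ± 1.91 (-2.90, SE 0.77, adjusted p = 0.134). It is in the gastrointestinal epithelium list (shift -0.32, exact permutation p = 0.488; -0.09 without control 4), and airway epithelium expresses it too.

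Herpud1, a gene of protein degradation at the endoplasmic reticulum, fell by 0.78 (SE 0.19) adjusted over the list alone (adjusted p = 0.131 over all probesets). The unfolded protein response list as a whole shifted by -0.02 (exact permutation p = 0.850), a value whose sign changed with the processing, with Canx at 0.23 (SE 0.08) and Creld2 at -0.56 (SE 0.21). Fas, a death receptor gene and p53 target, fell by 0.71 (SE 0.18) adjusted over the list alone (adjusted p = 0.132 over all probesets), while the list shifted by 0.04 (exact permutation p = 0.652), with a sign that changed with the arrays left out, and Ccng1 and Zmat3 of the same list differed by 0.33 (SE 0.13) and 0.41 (SE 0.18). The interferon response list shifted by -0.22 (exact permutation p = 0.362), -0.06 without deficient 3 and 6 and -0.60 with the 10 arrays without Y-linked signal, with Usp18 at -1.82 (SE 0.56), Ifi35 at -0.68 (SE 0.23) and Iigp1 at 0.66 (SE 0.30).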
